A study of Homo sapiens with 864 samples.

How the data were processed

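Gene expression was measured by RNA sequencing in T47D cells, a human breast cancer line. Per the labels, the cells were infected with lentivirus for 1 of 8 constructs, selected with puromycin, plated in 96-well plates, and kept for 48 h in medium with 10% charcoal-stripped serum. They were then treated for 24 h with DMSO, 1 µM fulvestrant, 1 µM neratinib, 10 µM palbociclib, or fulvestrant with neratinib or with palbociclib. Libraries were made with SMART-Seq2 from bead-purified lysates, per the labels' protocols. The 864 deposited samples are 288 libraries, each sequenced in 3 run sets, in 48 groups of 6 libraries. Sample numbers repeat the layout of groups every 96 numbers, which gives 3 blocks with 2 libraries of each group. They are called plate blocks here, though the labels do not say that a block was 1 plate.

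The authors aligned reads with STAR to hg19, per the labels. The STAR version, the counting tool, the gene annotation and any filter are not given in the sources used here. The authors deposited raw read counts for 52576 genes with versioned Ensembl identifiers, 1 table per run set, and all values were whole numbers. They also deposited tables of RPKM values for the same runs, which were left out because the counts of the same libraries were tested instead.

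The counts of the 3 run sets were summed per library. To check that the 3 run sets hold the same library, the variance of the split of a gene's counts over 2 runs was divided by that of counting noise. This ratio had a median of 1.99 for 846 pairs of runs of 1 library and of 5.93 for 691 pairs of libraries of 1 group. Libraries with fewer than 10% of the median reads were left out. This removed 6 libraries with 48 to 904 reads and kept 282, the shallowest of these at 16.2% of the median. Reads on genes per kept library were 1.14 to 9.73 M, median 7.03 M. At the median depth 1 CPM was 7.03 reads, so genes below 1 CPM rest on a few reads per library. Of counts from 2 to 11 in the first run set, 72.0% were even, as when both reads of a pair are counted, so the number of fragments is lower than the number of reads.

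Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM normalization, filterByExpr by group, glmQLFit and glmQLFTest). The fit had 1 column per group for the 48 groups, with 18225 genes tested, 234 residual degrees of freedom and 14.0 prior degrees of freedom. P values were adjusted with the Benjamini-Hochberg method over all tested genes, and genes passed at an adjusted p below 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. Levels are TMM-normalized CPM values, computed here from the deposited counts. The constructs were compared with GFP in DMSO, and the mean of the 4 activating mutants with HER2 WT and HER2 D845A. The drugs were compared with DMSO in GFP and the pairs with fulvestrant alone. Interaction terms tested whether a response differed from that in GFP. Single drugs in the other constructs were added after the data were seen. Whether the wells are separate infections is not given, so libraries were treated as replicate wells.

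Fixed lists held 395 genes in 21 lists. They were estrogen-induced, estrogen-repressed, MAPK output, immediate early, FOXO-activated, E2F and DNA replication, G2 and mitosis, cholesterol synthesis, fatty acid synthesis, glycolysis and hypoxia, and ATF4 and amino acid genes. The others were unfolded protein response, heat shock, ribosome biogenesis, lysosome, interferon response, antigen presentation, luminal identity, basal and mesenchymal, invasion and migration, and fibroblast, blood and vessel genes. Each was tested with camera (preset correlation of 0.01) on voom values in limma 3.58.1, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Where the text counts the members of a list that passed over all genes, it also gives, as alone, how many passed when adjusted over the list's members, and other list tests are given by their p. Scores are the mean over a list of log2(CPM + 1) per library. Scores were compared by exact two-sided permutation, adjusted over 987 comparisons, and the smallest exact p that 6 against 6 libraries can give is 0.00216. Of these comparisons 55.4% passed.

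Genes named in the text were chosen by a fixed rule. It names 14 genes in any comparison (ERBB2, ESR1, ERBB3, EGFR, CCND1, MYC, CDKN1A, CDK6, RB1, PGR, GREB1, TFF1, DUSP6 and MKI67). It adds the 10 largest and the 10 smallest log2 fold changes among genes that passed, averaged at least 10 CPM in a compared group and, in comparisons of 2 groups, did not overlap between groups. It also adds up to 4 members of each list with the smallest adjusted p. Genes without a symbol, pseudogenes and unnamed loci could be skipped, and the text names fewer than the rule allows. Gene names come from the deposited tables.

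The pipeline was tested on simulated data, drawn from the real gene means, library sizes and dispersion trend, with 200 of 18225 genes changed in 1 group of the comparison of fulvestrant with DMSO in GFP. The fit recovered 29.9% of genes changed 1.5-fold, 59.7% of those changed 2-fold and 80.3% of those changed 4-fold. It made 6 false calls, and 0 in a comparison with no change.

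The comparisons of the design, the depth threshold, the gene lists, the rule for named genes and the first set of alternatives were written before the data were examined. These alternatives were median-of-ratios (RLE) size factors, no low-count filter, a fit on the compared groups only and plate as replicate block. They also were the first run set alone, all libraries, libraries with at least 30% of the median depth, DESeq2 1.42.0 on the compared groups, and pseudocounts of 0.1 and 5 CPM for scores. Leaving out 1 library at a time, list tests with plate as block, plate as block on the compared groups for fulvestrant, and leaving out 2 GFP DMSO libraries of the third plate block were added after the data were seen. For each comparison 40 splits of its libraries, the real one included, were fitted on the compared groups. For the 15 fulvestrant comparisons 40 splits within plate blocks were also fitted on these groups with plate as block. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.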

Results

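RNA was sequenced from T47D cells, an estrogen receptor-positive, HER2-negative human breast cancer line that carried 1 of 8 lentiviral constructs. The constructs were GFP as control, wild-type HER2 (HER2 WT), HER2 D845A without kinase activity, 4 HER2 forms with activating mutations (S653C, L755S, V777L and L869R) and the ESR1 Y537S form of the estrogen receptor. Cells were kept for 48 h in medium with charcoal-stripped serum, which is low in estrogen, and then for 24 h in the vehicle DMSO or in drug. The drugs were 1 µM fulvestrant (degrades the estrogen receptor), 1 µM neratinib (blocks HER-family kinases), 10 µM palbociclib (blocks CDK4 and CDK6), or fulvestrant with either of the others. The 48 groups had 6 full-length (SMART-Seq2) libraries each, in 3 blocks of 96 sample numbers that are called plate blocks here. Each library was sequenced in 3 run sets, and the runs were summed. Depth was 1.14 to 9.73 M reads on genes per library, median 7.03 M. Of the libraries, 6 with 48 to 904 reads were left out, so GFP palbociclib had n = 4, while HER2 V777L fulvestrant, HER2 V777L palbociclib, HER2 D845A palbociclib and HER2 L755S fulvestrant with neratinib had n = 5. All other groups had n = 6.

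Changes are log2 fold changes ± standard error from edgeR over 18225 genes, with p values adjusted over all genes, and list tests are camera tests adjusted over the lists. Every comparison with GFP in DMSO used the 6 GFP DMSO libraries, so these comparisons are not independent of each other. The labels do not say whether wells came from separate infections, so the p values measure spread between wells, and by the sample numbers each construct and drug had the same place in every plate block, though the labels do not say that a block was 1 plate. Of the GFP DMSO libraries, 2 of the third plate block stood apart, with 5.88% and 6.70% mitochondrial reads against 4.55% at most elsewhere in the series, and with 45.2 and 27.4 CPM of ERBB2 against 91.3 CPM or more in the other 4. Values without these 2 libraries, a setting chosen after they were seen, are given where they end a call or move a count by over 1.5 times.

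The construct genes were compared first. ERBB2 (ENSG00000141736.7), which encodes HER2, averaged 93.7 CPM in GFP and 1496 CPM in HER2 WT, with 1123 CPM in HER2 D845A and 1404 to 2410 CPM in the 4 activating mutants, all in DMSO with n = 6. ESR1 (ENSG00000091831.15), the estrogen receptor gene, averaged 78.9 CPM in GFP and 449 CPM in ESR1 Y537S. ERBB2 rose by 4.0 ± 0.17 (adjusted p = 3.43e-61) in HER2 WT, and ESR1 rose by 2.51 ± 0.21 (adjusted p = 1.14e-24) in ESR1 Y537S. Counts do not separate the construct's transcript from the cell's own.

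**Figure D1:**
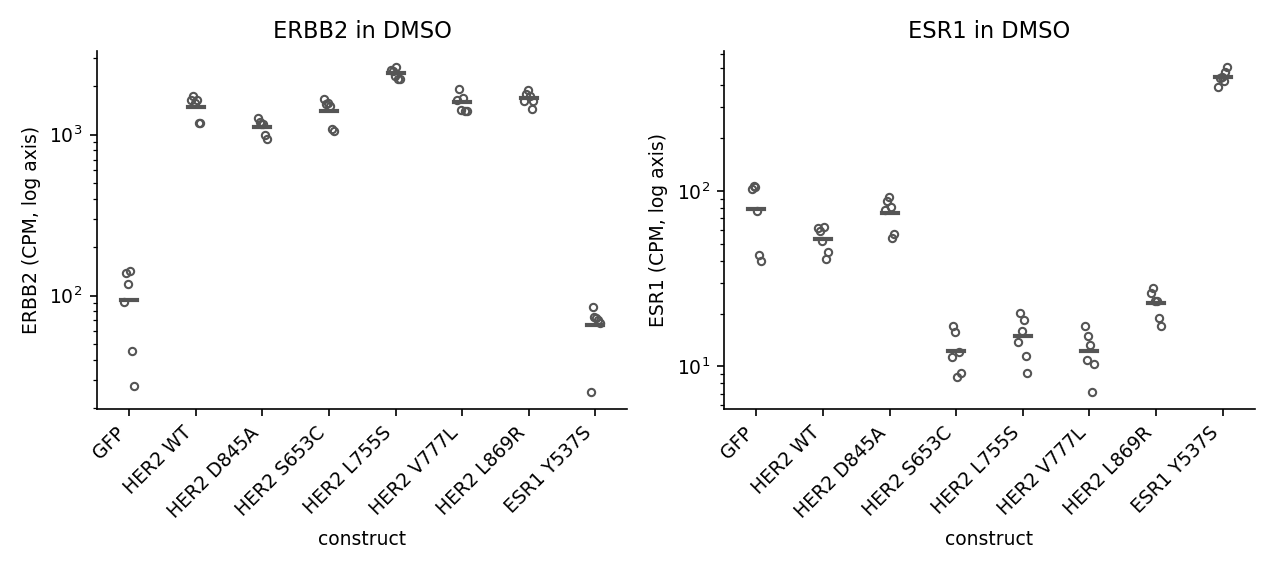
ERBB2 (left) and ESR1 (right) in CPM on a log axis in each DMSO library by construct, n = 6 libraries per construct, with a bar at the mean. ERBB2 averaged 93.7 CPM in GFP and 1123 to 2410 CPM in the 6 HER2 constructs, and ESR1 averaged 449 CPM in ESR1 Y537S.

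The next comparison asked what wild-type HER2 did without drug. In HER2 WT against GFP, 2544 genes passed, 1223 higher and 1321 lower. Without the 2 libraries 954 passed, 645 higher and 309 lower. On the compared groups DESeq2 called 525 and edgeR 0.933% of genes, and 1400 passed with the first run set alone. DUSP6 and DUSP4, phosphatases induced by ERK, rose by 3.05 ± 0.31 (adjusted p = 3.24e-16) and 2.27 ± 0.22 (adjusted p = 1.94e-17). The cell cycle inhibitor CDKN1A rose by 1.19 ± 0.14 and cyclin D1 (CCND1) by 1.31 ± 0.22. The secreted protein gene PIP changed by -1.96 ± 0.17 (adjusted p = 9.03e-21). Among ATF4 and amino acid genes 11 of 20 rose and 0 fell (12 and 1 adjusted over the list alone, adjusted p = 9.12e-11), with the serine enzyme PSAT1 at 1.60 ± 0.15 and the ATF4 target TRIB3 at 1.30 ± 0.17. Among fatty acid synthesis genes 8 of 11 rose and 0 fell (9 and 0 alone, adjusted p = 3.52e-06). Of immediate early genes 8 of 11 rose and 0 fell (8 and 1 alone, adjusted p = 7.62e-06), and of MAPK output genes 6 of 19 rose and 0 fell (7 and 0 alone, adjusted p = 2.26e-05). Estrogen-induced genes fell as a list, in which 2 of 40 rose and 7 fell (2 and 10 alone, adjusted p = 0.00274), with the scaffold gene PDZK1 at -2.33 ± 0.38. Of G2 and mitosis genes 0 of 30 rose and 7 fell (0 and 7 alone, adjusted p = 0.000164, adjusted p = 0.161 with an estimated correlation, adjusted p = 0.437 without the 2 libraries).

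Kinase-dead HER2 served as the control for HER2 protein without its signal. In HER2 D845A against GFP, 3487 genes passed, 1392 higher and 2095 lower, and without the 2 libraries 1005 passed, 602 higher and 403 lower. On the compared groups DESeq2 called 766 and edgeR 1.05% of genes, and 1970 passed with the first run set alone. CYP1A2 and CYP1A1, drug-metabolising enzymes induced through the aryl hydrocarbon receptor, rose by 4.10 ± 0.26 (adjusted p = 6.12e-36) and 2.69 ± 0.15 (adjusted p = 5.6e-42). The adhesion molecule L1CAM rose by 1.76 ± 0.20. The lipocalin APOD changed by -2.33 ± 0.18 (adjusted p = 2.5e-26) and CRISP3, a secreted glycoprotein gene, by -2.50 ± 0.23 (adjusted p = 9.03e-20). DUSP6 did not pass, at 0.70 ± 0.34 (adjusted p = 0.147). Of estrogen-induced genes 4 of 40 rose and 13 fell (4 and 14 adjusted over the list alone, adjusted p = 0.0312). Of immediate early genes 7 of 11 rose and 0 fell (8 and 0 alone, adjusted p = 0.000349), and of G2 and mitosis genes 0 of 30 rose and 10 fell (0 and 11 alone, adjusted p = 1.71e-05, adjusted p = 0.175 with an estimated correlation, adjusted p = 0.0529 without the 2 libraries). Among luminal identity genes 5 of 15 rose and 1 fell (5 and 1 alone, adjusted p = 0.0371, adjusted p = 0.127 without the 2 libraries).

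The 4 activating mutants were each compared with GFP to see what they did without drug. S653C changed 6471 genes (3289 higher, 3182 lower), L755S 5858 (2928, 2930), V777L 6510 (3229, 3281) and L869R 4573 (2238, 2335). Without the 2 libraries the splits were 2917 and 2218, 2412 and 1813, 2829 and 2232, and 1861 and 1369. Fitted on the compared groups only, the counts were 3523, 2609, 3360 and 1368, and DESeq2 called 3527 for L755S, 4149 for V777L and 2085 for L869R, where 2842 passed with the first run set alone. SPRY4, a feedback inhibitor of the pathway from growth factor receptors to ERK, rose by 7.83 ± 0.61, 7.70 ± 0.61, 7.57 ± 0.61 and 7.14 ± 0.63 in S653C, L755S, V777L and L869R. DUSP6 rose by 5.70 ± 0.33 (adjusted p = 1.6e-42), 5.93 ± 0.33 (adjusted p = 3.05e-44), 5.74 ± 0.33 (adjusted p = 8.53e-43) and 5.60 ± 0.32 (adjusted p = 3.98e-41) in that order. LCN2, an iron carrier protein, rose by 7.33 ± 0.50, 5.61 ± 0.53, 7.01 ± 0.51 and 5.68 ± 0.53. The progesterone receptor gene PGR changed by -3.61 ± 0.24 (adjusted p = 3.13e-35), -3.21 ± 0.23 (adjusted p = 1.46e-30), -3.32 ± 0.23 (adjusted p = 9.4e-32) and -3.12 ± 0.23 (adjusted p = 1.22e-28), and the estrogen-induced gene GREB1 by -3.23 ± 0.26, -2.98 ± 0.25, -3.0 ± 0.25 and -2.17 ± 0.24. ESR1 itself changed by -2.67 ± 0.22, -2.40 ± 0.22, -2.69 ± 0.22 and -1.78 ± 0.21. CCND1 rose by 2.57 ± 0.22, 2.44 ± 0.22, 2.40 ± 0.22 and 1.89 ± 0.22. MYC, a growth regulator, fell in each, from -1.33 ± 0.25 in V777L to -2.01 ± 0.26 in L755S.

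MAPK output genes rose in every activating mutant. In S653C 17 of 19 rose and 1 fell (17 and 1 adjusted over the list alone, adjusted p = 3.57e-15), and in L755S 15 of 19 rose and 1 fell (16 and 1 alone, adjusted p = 3.17e-14). In V777L 17 of 19 rose and 1 fell (17 and 1 alone, adjusted p = 5.5e-16), and in L869R 13 of 19 rose and 1 fell (13 and 1 alone, adjusted p = 7.46e-15). Estrogen-induced genes fell as a list. In S653C 7 of 40 rose and 22 fell (7 and 24 alone, adjusted p = 0.000118), in L755S 8 of 40 rose and 23 fell (8 and 24 alone, adjusted p = 5.52e-05), in V777L 6 of 40 rose and 23 fell (6 and 23 alone, adjusted p = 0.000269) and in L869R 5 of 40 rose and 19 fell (5 and 20 alone, adjusted p = 3.29e-06). Within this list AREG, which encodes an EGFR ligand, went the other way and rose by 3.63 ± 0.26 in S653C and 3.67 ± 0.26 in V777L. Estrogen-repressed genes also fell (adjusted p = 0.0015 in S653C, adjusted p = 0.00117 in L755S, adjusted p = 0.0154 in V777L, adjusted p = 0.000587 in L869R). E2F and DNA replication genes rose while G2 and mitosis genes fell. For the former, 14 of 30 rose and 0 fell (14 and 0 alone, adjusted p = 9.34e-07) in L755S and 13 of 30 rose and 0 fell (17 and 0 alone, adjusted p = 5.78e-08) in L869R, and the list passed in S653C (adjusted p = 0.000118, adjusted p = 0.069 with an estimated correlation) and V777L (adjusted p = 0.00814, adjusted p = 0.21 with an estimated correlation). For the latter, 0 of 30 rose and 22 fell (0 and 22 alone, adjusted p = 6.07e-12) in V777L, and the list passed in S653C (adjusted p = 5.43e-06, adjusted p = 0.069 with an estimated correlation), L755S (adjusted p = 1.25e-09) and L869R (adjusted p = 1.71e-08).

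Of interferon response genes 23 of 24 rose and 0 fell (23 and 0 adjusted over the list alone, adjusted p = 7.99e-15) in V777L and 19 of 24 rose and 0 fell (22 and 0 alone, adjusted p = 0.000151, adjusted p = 0.308 with an estimated correlation) in S653C, and the list did not pass in L869R (adjusted p = 0.0875) or L755S (adjusted p = 0.422). Of antigen presentation genes 11 of 12 rose and 0 fell (11 and 0 alone, adjusted p = 5.5e-16) in V777L. Among basal and mesenchymal genes 6 of 14 rose and 2 fell (6 and 2 alone, adjusted p = 0.00868) in V777L, with the annexin ANXA1 at 3.31 ± 0.20. The luminal keratins KRT8 and KRT18 rose by 1.54 ± 0.12 and 1.73 ± 0.14 in S653C, and the luminal identity list passed in V777L (adjusted p = 0.0215, adjusted p = 0.0589 without the 2 libraries). Of invasion and migration genes 7 of 13 rose and 0 fell (8 and 0 alone, adjusted p = 0.0015) in S653C, with L1CAM at 3.55 ± 0.20. Of FOXO-activated genes 1 of 12 rose and 7 fell (1 and 7 alone, adjusted p = 0.0053) in S653C, with the repressor BCL6 at -1.69 ± 0.13. Heat shock genes rose as a list in V777L (adjusted p = 0.00107). The ribosome biogenesis (adjusted p = 0.326) and cholesterol synthesis (adjusted p = 0.239) lists did not pass in V777L, and the glycolysis and hypoxia list did (adjusted p = 0.0262, adjusted p = 0.216 with an estimated correlation). Of the markers of fibroblasts, blood and vessels, LUM rose by 4.05 ± 0.32 and DCN changed by -3.66 ± 0.88 in S653C.

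The ESR1 Y537S receptor, a form active without estrogen, changed 4686 genes against GFP, 2317 higher and 2369 lower (1828 and 1496 without the 2 libraries). On the compared groups only 1755 passed, DESeq2 called 2452, and 3113 passed with the first run set alone. The transglutaminase gene TGM2 rose by 6.83 ± 0.57 (adjusted p = 1.01e-23), the transporter gene ABCG2 by 4.90 ± 0.37 and the surface antigen gene CD34 by 6.88 ± 0.86. PIP changed by -3.85 ± 0.19 (adjusted p = 7.64e-52) and the methyltransferase gene GNMT by -4.28 ± 0.26. GREB1 rose by 0.72 ± 0.23 (adjusted p = 0.0103), but did not pass on the compared groups only (adjusted p = 0.167), by DESeq2 (adjusted p = 0.141) or without the 2 libraries (adjusted p = 0.333). PGR did not pass, at 0.32 ± 0.20 (adjusted p = 0.263). Of estrogen-induced genes 26 of 40 rose and 1 fell (31 and 2 adjusted over the list alone, adjusted p = 1.76e-22), with the chaperone HSPB8 at 1.88 ± 0.13, PDZK1 at 3.75 ± 0.34 and the neuropeptide receptor NPY1R at 3.60 ± 0.37. Estrogen-repressed genes fell as a list (adjusted p = 1.55e-06), with the cytokine receptor IL1R1 at -3.24 ± 0.27. Of ATF4 and amino acid genes 14 of 20 rose and 1 fell (15 and 1 alone, adjusted p = 7.24e-09). Of FOXO-activated genes 1 of 12 rose and 7 fell (1 and 8 alone, adjusted p = 8.02e-05), with the ubiquitin ligase gene FBXO32 at -3.60 ± 0.19. Lysosome genes fell as a list (adjusted p = 0.0135, adjusted p = 0.312 with an estimated correlation). The MAPK output list did not pass (adjusted p = 0.373).

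To ask what the mutations added to HER2 itself, the mean of the 4 activating mutants was compared with HER2 WT and with HER2 D845A. Against HER2 WT 3058 genes passed, 1561 higher and 1497 lower, and 1849 passed with the first run set alone. ERBB2 did not pass, at 0.21 ± 0.12 (adjusted p = 0.242). DUSP6 was higher by 2.69 ± 0.24 (adjusted p = 1.57e-21) and CCND1 by 1.01 ± 0.17. PGR differed by -2.56 ± 0.15 (adjusted p = 8.21e-40), ESR1 by -1.83 ± 0.15 (adjusted p = 2.53e-24), GREB1 by -2.30 ± 0.17, the insulin-like growth factor binding protein IGFBP5 by -2.83 ± 0.09 and the corticosteroid carrier SERPINA6 by -3.38 ± 0.15. Of MAPK output genes 16 of 19 were higher and 1 lower (17 and 1 adjusted over the list alone, adjusted p = 1.78e-22). Of cholesterol synthesis genes 0 of 20 were higher and 8 lower (0 and 11 alone, adjusted p = 7.5e-05), with the enzyme LSS at -1.02 ± 0.11. Of interferon response genes 17 of 24 were higher and 0 lower (20 and 0 alone, adjusted p = 9.39e-08, adjusted p = 0.17 with an estimated correlation). Against HER2 D845A 6158 genes passed, 3223 higher and 2935 lower (2514 and 3434 without a low-count filter). DUSP4 was higher by 5.60 ± 0.23 (adjusted p = 4.33e-64), PGR differed by -3.93 ± 0.14 (adjusted p = 1.08e-72) and SCUBE2, a secreted signalling protein gene, by -5.19 ± 0.22. Of E2F and DNA replication genes 28 of 30 were higher and 0 lower (28 and 0 alone, adjusted p = 7.28e-15), and of estrogen-induced genes 7 of 40 were higher and 15 lower (7 and 19 alone, adjusted p = 0.00127).

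The 4 activating mutants also differed among themselves, with 716 genes past the test of any difference. With plate as block 1319 passed, with the first run set alone 435, and DESeq2 called 1215. KIAA1324 (adjusted p = 1.01e-44), CD74, which chaperones class II molecules (adjusted p = 6.13e-38), the receptor GPRC5A (adjusted p = 1.78e-36) and IGFBP5 (adjusted p = 7.31e-29) were among them. ERBB2 passed (adjusted p = 8.73e-05), while PGR did not (adjusted p = 0.742).

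Fulvestrant in GFP cells gave the response of the control line to loss of the receptor. The test called 2177 genes, 884 higher and 1293 lower. Without the 2 libraries 353 passed, 56.4% of them higher, on the compared groups only 34 passed, 3 higher and 31 lower, and 90 passed there with plate as block. In the fit on all groups 3316 passed with plate as block, 1158 with the first run set alone and 1324 without a low-count filter, and DESeq2 called 0.900% of genes. The chemokine CXCL12 changed by -3.92 ± 0.26 (adjusted p = 2.2e-33), SERPINA6 by -2.61 ± 0.23 (adjusted p = 1.26e-20) and the secreted protein gene OLFM1 by -3.31 ± 0.36. PGR changed by -1.05 ± 0.21 (adjusted p = 6.47e-05) and GREB1 by -1.70 ± 0.24 (adjusted p = 9.23e-09). CYP1A1 rose by 2.57 ± 0.15 (adjusted p = 3.56e-39). TFF1, a secreted estrogen-induced peptide gene, averaged 0.850 CPM in DMSO and was listed at 0 CPM in the fulvestrant libraries, so no fold change is given for it. Of estrogen-induced genes 1 of 40 rose and 23 fell (1 and 26 adjusted over the list alone, adjusted p = 3.47e-20). Of E2F and DNA replication genes 0 of 30 rose and 11 fell (0 and 15 alone, adjusted p = 4.5e-07), and of G2 and mitosis genes 0 of 30 rose and 10 fell (0 and 18 alone, adjusted p = 4.05e-14). Among ribosome biogenesis genes 1 of 18 rose and 10 fell (1 and 13 alone, adjusted p = 6.7e-08).

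Fulvestrant was then compared with DMSO within each other construct, in contrasts added after the data were seen. In HER2 WT 48 genes passed (1150 at unadjusted p under 0.05) and in HER2 D845A 54 (1165). With plate as block 0.872% and 0.571% of genes passed, DESeq2 called 0.636% and 0.691%, and with the first run set alone 26 and 24 genes passed. With plate as block on the compared groups only, 434 and 428 passed. CXCL12 changed by -3.36 ± 0.25 in HER2 WT and -2.63 ± 0.23 in HER2 D845A, and GREB1 by -1.58 ± 0.24 and -1.55 ± 0.24. The activating mutants had 3 genes in S653C (545 at unadjusted p under 0.05), 3 in L755S (644), 3 in V777L (659) and 17 in L869R (971). DESeq2 called 5, 7, 4 and 42, with plate as block 6, 9, 3 and 25 passed, and on the compared groups only 2, 3, 1 and 13 passed, or 7, 35, 10 and 0.850% of genes with plate as block there. CYP1A1 rose by 1.69 ± 0.14, 1.95 ± 0.14, 1.38 ± 0.15 and 2.34 ± 0.15 in S653C, L755S, V777L and L869R. IGFBP5 changed by -0.98 ± 0.14 in L755S and -0.88 ± 0.13 in L869R, and by -0.65 ± 0.14 (adjusted p = 0.0437) in S653C and -0.68 ± 0.15 (adjusted p = 0.0483) in V777L, where 6 and 7 of the 8 other settings did not call it. SERPINA6 changed by -1.64 ± 0.26 in S653C and -1.79 ± 0.25 in L869R, and CISH, a cytokine signalling inhibitor gene, by -1.24 ± 0.21 in L755S, which did not pass with the first run set alone (adjusted p = 0.969). S100A7A, a gene of the S100 family, rose by 2.93 ± 0.52 (adjusted p = 0.000499) in V777L to 7.28 CPM and is named because it completes the 3, so it was chosen after its values were seen, and it did not pass on the compared groups only (adjusted p = 0.725). In ESR1 Y537S 2556 genes passed, 1293 higher and 1263 lower, and 1484 with the first run set alone. There TGM2 changed by -5.76 ± 0.50 (adjusted p = 1.6e-21), PDZK1 by -3.77 ± 0.33, STC2, a secreted hormone gene, by -2.0 ± 0.11 (adjusted p = 1.21e-42) and CD34 by -5.02 ± 0.71, while ERBB2 rose by 1.13 ± 0.15. Of estrogen-induced genes 0 of 40 rose and 29 fell (1 and 31 adjusted over the list alone, adjusted p = 4.75e-54) in ESR1 Y537S, and of G2 and mitosis genes 0 of 30 rose and 26 fell (0 and 29 alone, adjusted p = 3.26e-35).

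**Figure D2:**
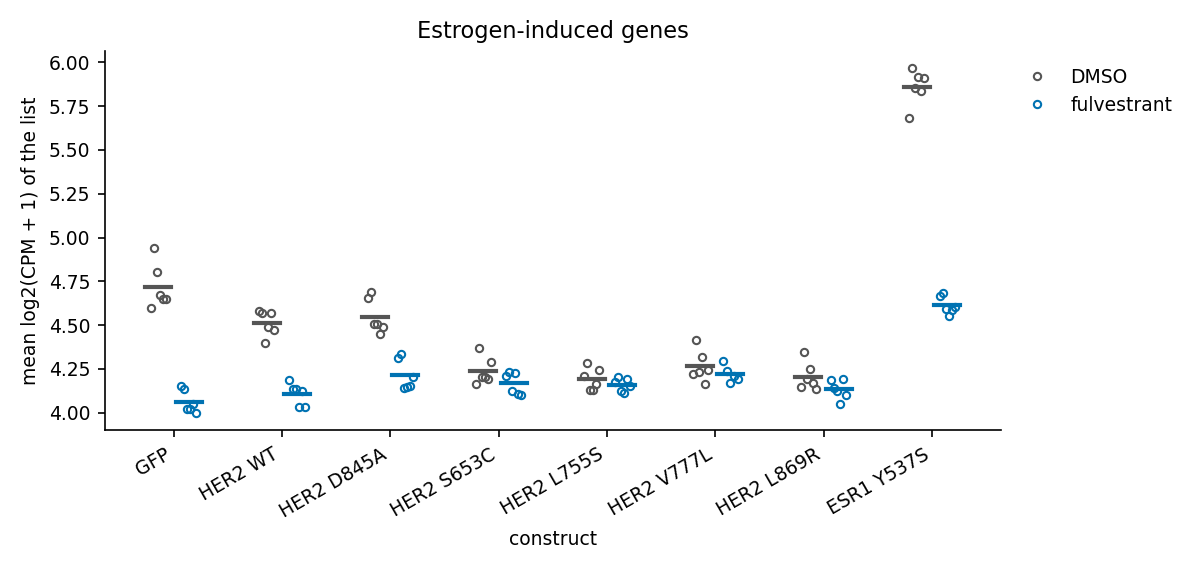
Mean log2(CPM + 1) of the 40 estrogen-induced genes in each library, by construct, in DMSO and in fulvestrant, with a bar at the group mean and n = 5 or 6 libraries per group. The group mean was 4.72 in GFP DMSO and 4.06 in GFP fulvestrant, and 4.19 to 4.27 in the 4 activating mutants in DMSO.

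Whether a construct altered the fulvestrant response was tested by the difference between its response and that of GFP. The test called 499 genes for S653C, 365 for L755S, 410 for V777L, 0.741% of genes for L869R and 447 for ESR1 Y537S. For HER2 WT and HER2 D845A it called 85 and 0.554% of genes. Without the 2 libraries the counts were 48, 39, 43 and 26 for the 4 activating mutants, 0.955% of genes for ESR1 Y537S, and edgeR called 0 for HER2 WT and HER2 D845A (700 and 851 at unadjusted p under 0.05), where DESeq2 with all kept libraries called 2 and 3. On the compared groups only, edgeR called 18, 10, 11 and 5 for the 4 activating mutants, 73 for ESR1 Y537S and 0 for HER2 WT and HER2 D845A (830 and 862 at unadjusted p under 0.05), while DESeq2 called 55, 34, 39 and 21 for the mutants and 1.11% of genes for ESR1 Y537S. With plate as block counts were higher in the fit on all groups, from 584 for HER2 WT to 1299 for S653C, but on the compared groups only they were 29, 24, 20 and 12 for the mutants, 0.823% of genes for ESR1 Y537S and 0 for HER2 WT and HER2 D845A (1173 and 1303 at unadjusted p under 0.05). With the first run set alone or without a low-count filter each was at most 1.39% of genes. CXCL12 responses were less negative than in GFP by 2.66 ± 0.39 in S653C, 3.39 ± 0.37 (adjusted p = 3.84e-13) in L755S, 2.87 ± 0.39 in V777L and 2.47 ± 0.37 in L869R. OLFM1 differed by 3.47 ± 0.47 in S653C, 3.14 ± 0.48 in L755S and 3.17 ± 0.49 in V777L. CXCL12 averaged 48.6 CPM in GFP DMSO and 3.41 CPM in GFP fulvestrant, against 5.03 to 8.34 CPM in DMSO and 2.09 to 3.77 CPM in fulvestrant in the 4 activating mutants. Of estrogen-induced genes 11 of 40 were higher and 0 lower (18 and 2 adjusted over the list alone, adjusted p = 2.28e-13) in S653C, 11 of 40 were higher and 0 lower (19 and 1 alone, adjusted p = 1.23e-14) in L755S, 13 of 40 were higher and 1 lower (20 and 1 alone, adjusted p = 4.58e-14) in V777L and 10 of 40 were higher and 0 lower (17 and 1 alone, adjusted p = 1.93e-14) in L869R. In HER2 WT 1 of 40 were higher and 0 lower (2 and 0 alone, adjusted p = 0.00149), and in HER2 D845A 3 of 40 were higher and 0 lower (10 and 0 alone, adjusted p = 6.2e-06). In ESR1 Y537S the response of this list was more negative than in GFP, and 1 of 40 were higher and 5 lower (3 and 10 alone, adjusted p = 3.28e-06), with TGM2 at -6.37 ± 0.93.

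Neratinib in GFP cells changed 5097 genes, 2147 higher and 2950 lower. The count was 3178 without the 2 libraries, 1830 on the compared groups only and 2664 by DESeq2. GDF15 rose by 3.19 ± 0.23 (adjusted p = 1.25e-30), the stress factor DDIT3 by 2.43 ± 0.14 (adjusted p = 1.96e-41), TRIB3 by 2.76 ± 0.17 and GPNMB, a lysosomal glycoprotein gene, by 2.60 ± 0.12. The receptor gene ERBB3 rose by 0.95 ± 0.12. The replication licensing genes CDC6 and MCM10 changed by -3.43 ± 0.21 and -3.63 ± 0.31 and the proliferation marker MKI67 by -2.0 ± 0.22. Of E2F and DNA replication genes 0 of 30 rose and 30 fell (0 and 30 adjusted over the list alone, adjusted p = 2.68e-77), and of G2 and mitosis genes 0 of 30 rose and 30 fell (0 and 30 alone, adjusted p = 2.16e-60). Of ATF4 and amino acid genes 16 of 20 rose and 0 fell (16 and 1 alone, adjusted p = 1.57e-19). Lysosome genes rose as a list (adjusted p = 2.63e-07). Cholesterol synthesis (adjusted p = 2.05e-05), estrogen-induced (adjusted p = 2.05e-05), ribosome biogenesis (adjusted p = 9.82e-07) and glycolysis and hypoxia (adjusted p = 0.000188) lists fell.

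In the mean of the 4 activating mutants, a contrast added after the data were seen, neratinib changed 10639 genes, 5309 higher and 5330 lower. SPRY4 changed by -6.70 ± 0.27 (adjusted p = 4.71e-66), DUSP6 by -6.43 ± 0.17 (adjusted p = 1.55e-102), DUSP4 by -4.52 ± 0.11 and CCND1 by -2.80 ± 0.11 (adjusted p = 1.23e-67). GPNMB rose by 3.54 ± 0.06 (adjusted p = 1.46e-139), the heme-degrading enzyme gene HMOX1 by 3.02 ± 0.10 and PIK3IP1, which restrains PI3K, by 2.86 ± 0.10. ESR1 rose by 0.44 ± 0.11 and PGR by 0.36 ± 0.12. Of MAPK output genes 0 of 19 rose and 18 fell (0 and 18 adjusted over the list alone, adjusted p = 1.71e-17). Of E2F and DNA replication genes 0 of 30 rose and 30 fell (0 and 30 alone, adjusted p = 3.18e-62), and of lysosome genes 18 of 21 rose and 1 fell (18 and 1 alone, adjusted p = 1.77e-18). Of FOXO-activated genes 8 of 12 rose and 1 fell (8 and 1 alone, adjusted p = 0.000255), and of invasion and migration genes 0 of 13 rose and 10 fell (0 and 10 alone, adjusted p = 0.00143). Of interferon response genes 0 of 24 rose and 20 fell (0 and 21 alone, adjusted p = 0.0158, adjusted p = 0.562 with an estimated correlation). Of estrogen-induced genes 14 of 40 rose and 15 fell (14 and 17 alone, adjusted p = 0.244), and this list did not pass.

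**Figure D3:**
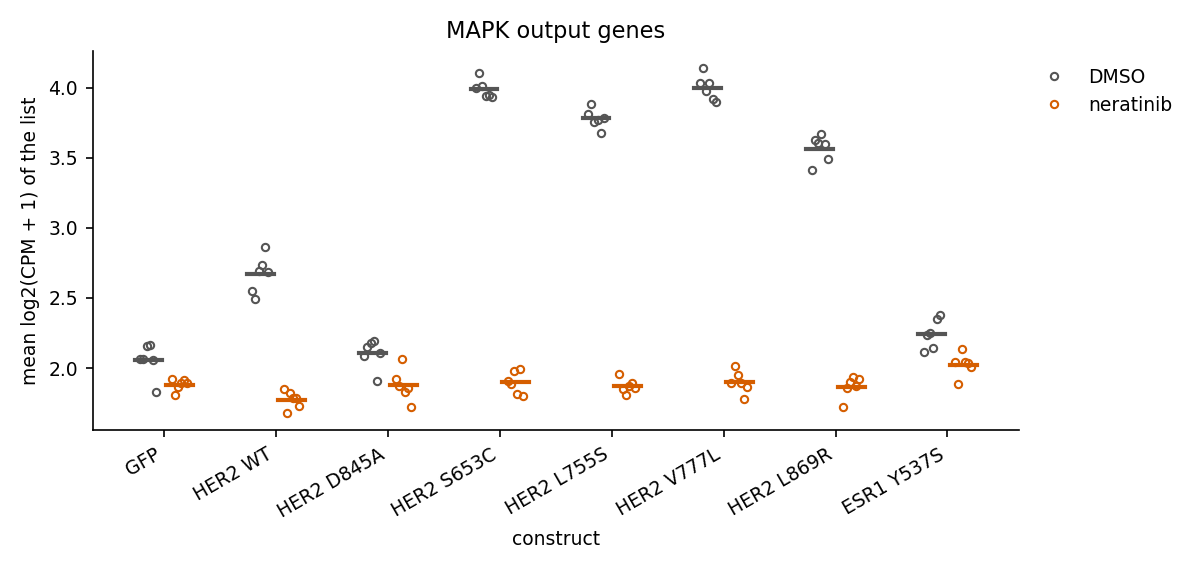
Mean log2(CPM + 1) of the 19 MAPK output genes in each library, by construct, in DMSO and in neratinib, with a bar at the group mean and n = 6 libraries per group. The group means were 3.57 to 4.0 in the 4 activating mutants, 2.67 in HER2 WT and 2.06 in GFP in DMSO, and 1.77 to 2.02 in the 8 constructs in neratinib.

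The neratinib response differed between the activating mutants and GFP for 3115 genes, 1694 higher and 1421 lower, and for 1548 without the 2 libraries, 672 higher and 876 lower. It was 1837 with the first run set alone. DUSP6 differed by -5.28 ± 0.50 (adjusted p = 8.95e-19), CCND1 by -2.21 ± 0.25 (adjusted p = 1.16e-13) and ESR1 by 1.17 ± 0.23, while the galactose enzyme gene GALM was higher by 2.18 ± 0.18. Of MAPK output genes 0 of 19 were higher and 11 lower (0 and 12 adjusted over the list alone, adjusted p = 8.17e-17). Cholesterol synthesis genes went the other way than in GFP, where they fell, and 16 of 20 were higher and 1 lower (17 and 1 alone, adjusted p = 1.43e-15), with HSD17B7 at 1.91 ± 0.19 and SQLE at 1.17 ± 0.13. Of ATF4 and amino acid genes 2 of 20 were higher and 10 lower (2 and 10 alone, adjusted p = 7.83e-08), with CHAC1, a glutathione-degrading enzyme gene, at -2.34 ± 0.27. Of luminal identity genes 1 of 15 were higher and 7 lower (1 and 8 alone, adjusted p = 2.68e-06), with KRT18 at -1.53 ± 0.16.

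For HER2 WT the neratinib response differed from that in GFP for 414 genes, and 86 without the 2 libraries. CHAC1 differed by -2.78 ± 0.33 (adjusted p = 3.8e-11) and ADM2, a peptide hormone gene, by -2.36 ± 0.33. Of ATF4 and amino acid genes 0 of 20 were higher and 10 lower (1 and 13 adjusted over the list alone, adjusted p = 2.19e-22). For ESR1 Y537S it differed for 646 genes, and 0.598% of genes without the 2 libraries. CXCL12 was higher by 2.0 ± 0.29, and the exchange factor RAPGEF3 differed by -2.37 ± 0.27. Of estrogen-induced genes 8 of 40 were higher and 0 lower (11 and 0 alone, adjusted p = 4.65e-11), and of unfolded protein response genes 5 of 14 were higher and 0 lower (10 and 0 alone, adjusted p = 2.74e-07). For HER2 WT and ESR1 Y537S the counts were 22 and 30 on the compared groups only, 0.351% and 0.609% of genes by DESeq2, 1.06% and 1.44% with the first run set alone, 1.16% and 1.65% without a low-count filter, and 999 and 1560 genes with plate as block.

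Palbociclib in GFP cells (n = 4 against 6) changed 4174 genes, 1848 higher and 2326 lower (1556 and 1446 without the 2 libraries). On the compared groups only 952 passed, DESeq2 called 1573, and 2769 passed with the first run set alone. CYP1A1 rose by 4.21 ± 0.17 (adjusted p = 1.75e-66) and GPNMB by 3.37 ± 0.13 (adjusted p = 6.07e-68). The ribonucleotide reductase gene RRM2 changed by -5.56 ± 0.31 (adjusted p = 4.67e-44), the mitotic gene NUSAP1 by -4.67 ± 0.24 and MKI67 by -3.84 ± 0.29. Of G2 and mitosis genes 0 of 30 rose and 30 fell (0 and 30 adjusted over the list alone, adjusted p = 3.07e-104), and of E2F and DNA replication genes 0 of 30 rose and 30 fell (0 and 30 alone, adjusted p = 1.28e-78). Among cholesterol synthesis genes 17 of 20 rose and 1 fell (18 and 1 alone, adjusted p = 7.39e-26), with LSS at 2.34 ± 0.16 and MVD at 2.37 ± 0.17. Of lysosome genes 16 of 21 rose and 1 fell (18 and 1 alone, adjusted p = 3.01e-22), and of fatty acid synthesis genes 6 of 11 rose and 0 fell (6 and 0 alone, adjusted p = 0.00133). Among markers of fibroblasts, blood and vessels, which rose as a list (adjusted p = 0.0467, adjusted p = 0.071 with plate as block) in the same libraries as the lysosome and cholesterol synthesis lists, LUM rose by 2.31 ± 0.36.

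In the mean of the 4 activating mutants, a contrast added after the data were seen, palbociclib changed 7367 genes, 3837 higher and 3530 lower. MVD rose by 2.72 ± 0.08 (adjusted p = 2.16e-90), CYP1A1 by 2.86 ± 0.07, GPNMB by 2.48 ± 0.06 and CCND1 by 0.80 ± 0.10. FAM111B, a protease gene active in replication, changed by -5.35 ± 0.19 and MKI67 by -3.60 ± 0.12. Of cholesterol synthesis genes 20 of 20 rose and 0 fell (20 and 0 adjusted over the list alone, adjusted p = 1.3e-53), and of lysosome genes 20 of 21 rose and 0 fell (20 and 0 alone, adjusted p = 1.92e-25). Of E2F and DNA replication genes 0 of 30 rose and 30 fell (0 and 30 alone, adjusted p = 1.47e-102). Of interferon response genes 19 of 24 rose and 0 fell (20 and 1 alone, adjusted p = 8.06e-05, adjusted p = 0.517 with an estimated correlation). The response differed from that in GFP for 1362 genes, 858 higher and 504 lower, for 379 without the 2 libraries, of which 39.6% were higher, for 421 without GFP DMSO replicate 6 alone, of which 50.4% were higher, for 2758 with plate as block, for 620 on the compared groups only, for 721 with the first run set alone and for 813 without a low-count filter. MYBL2, a mitotic transcription factor gene, differed by 1.91 ± 0.33 (adjusted p = 1.26e-05) and CYP1A2 by -1.64 ± 0.30. Among cholesterol synthesis genes 9 of 20 were higher and 0 lower (9 and 0 alone, adjusted p = 2.1e-08), with ACAT2 at 1.24 ± 0.17. Of estrogen-induced genes 9 of 40 were higher and 0 lower (14 and 0 alone, adjusted p = 1.44e-05).

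**Figure D4:**
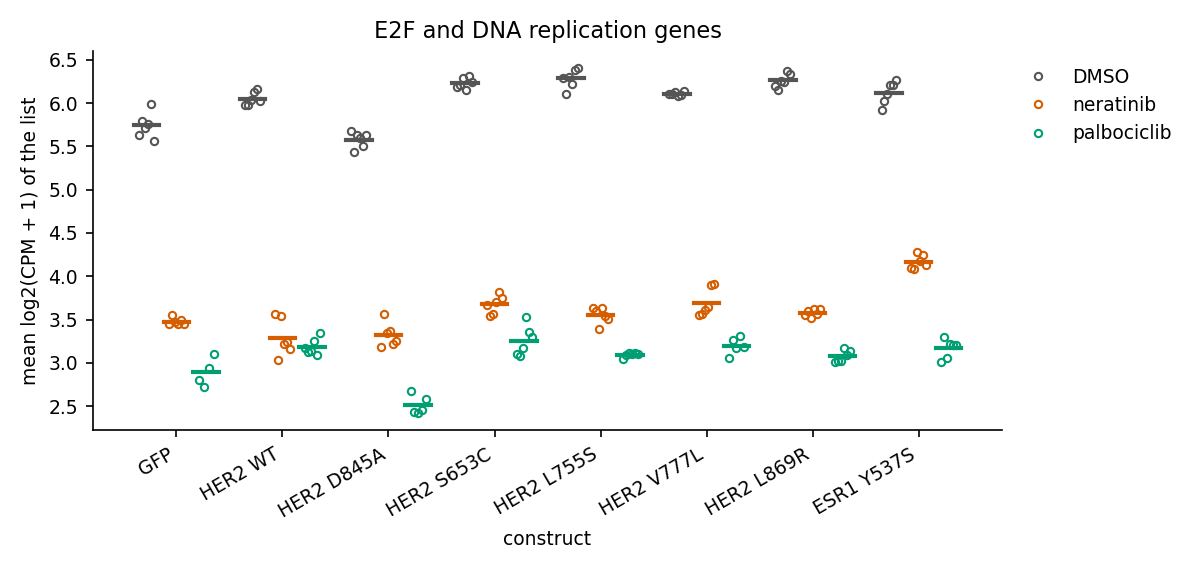
Mean log2(CPM + 1) of the 30 E2F and DNA replication genes in each library, by construct, in DMSO, neratinib and palbociclib, with a bar at the group mean and n = 4 to 6 libraries per group. The group means over the 8 constructs were 5.58 to 6.29 in DMSO, 3.29 to 4.17 in neratinib and 2.51 to 3.26 in palbociclib.

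The drug pairs were compared with DMSO in GFP. Fulvestrant with neratinib changed 5362 genes, 2328 higher and 3034 lower (1861 on the compared groups only, 2561 by DESeq2, 3536 with the first run set alone). GDF15 rose by 3.49 ± 0.23, CYP1A1 by 3.09 ± 0.15, and SERPINA6 changed by -4.11 ± 0.25, GREB1 by -2.24 ± 0.25 and PGR by -1.51 ± 0.21. Of estrogen-induced genes 0 of 40 rose and 23 fell (2 and 25 adjusted over the list alone, adjusted p = 5.5e-11), and of E2F and DNA replication genes 0 of 30 rose and 30 fell (0 and 30 alone, adjusted p = 7.89e-75). Fulvestrant with palbociclib changed 5325 genes, 2260 higher and 3065 lower (3315 without the 2 libraries, 2116 on the compared groups only, 2955 by DESeq2). CYP1A1 rose by 4.35 ± 0.16, and RRM2 changed by -5.47 ± 0.25, OLFM1 by -4.76 ± 0.40 and GREB1 by -2.31 ± 0.24. Of estrogen-induced genes 2 of 40 rose and 27 fell (2 and 27 alone, adjusted p = 3.02e-12), and of cholesterol synthesis genes 19 of 20 rose and 1 fell (19 and 1 alone, adjusted p = 5.46e-30).

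Each pair was also compared with fulvestrant alone, which leaves out the GFP DMSO libraries. In GFP, adding neratinib changed 2546 genes, 992 higher and 1554 lower, and 1432 with the first run set alone. DDIT3 rose by 2.54 ± 0.14, GDF15 by 2.97 ± 0.22, and CDC6 changed by -3.17 ± 0.21. Of ATF4 and amino acid genes 15 of 20 rose and 0 fell (16 and 0 adjusted over the list alone, adjusted p = 6.71e-27), and of MAPK output genes 0 of 19 rose and 7 fell (1 and 8 alone, adjusted p = 0.00669). In the activating mutants it changed 10466 genes, 5141 higher and 5325 lower. DUSP6 changed by -6.50 ± 0.18 (adjusted p = 1.07e-98), SPRY4 by -6.44 ± 0.28 and CCND1 by -2.93 ± 0.12. Of MAPK output genes 0 of 19 rose and 17 fell (0 and 17 alone, adjusted p = 3.58e-18). The 2 responses differed for 1692 genes, 792 higher and 900 lower in the mutants (2554 with plate as block, 861 with the first run set alone). DUSP6 differed by -4.76 ± 0.53 (adjusted p = 4.98e-14), CCND1 by -2.01 ± 0.26 (adjusted p = 1.45e-10) and GDF15 by -2.73 ± 0.24. Of cholesterol synthesis genes 15 of 20 were higher and 0 lower (18 and 0 alone, adjusted p = 1.64e-16), and of lysosome genes 12 of 21 were higher and 0 lower (17 and 0 alone, adjusted p = 8.27e-14).

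Adding palbociclib to fulvestrant changed 2959 genes in GFP, 1302 higher and 1657 lower, and 1865 with the first run set alone. LSS rose by 2.69 ± 0.15, GPNMB by 3.09 ± 0.12, and RRM2 changed by -5.09 ± 0.25. Among cholesterol synthesis genes 18 of 20 rose and 0 fell (19 and 0 adjusted over the list alone, adjusted p = 2.46e-61), and of G2 and mitosis genes 0 of 30 rose and 30 fell (0 and 30 alone, adjusted p = 1.51e-108). In the activating mutants it changed 7117 genes, 3666 higher and 3451 lower. MVD rose by 2.94 ± 0.08, GPNMB by 2.41 ± 0.06, and FAM111B changed by -5.42 ± 0.19. Of cholesterol synthesis genes 20 of 20 rose and 0 fell (20 and 0 alone, adjusted p = 3.77e-69), and of lysosome genes 20 of 21 rose and 0 fell (20 and 0 alone, adjusted p = 1.67e-28).

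List scores per library gave each construct's drug response by an exact two-sided permutation test, adjusted over the family of list comparisons. With fulvestrant the estrogen-induced score changed by -0.66 in GFP, -0.40 in HER2 WT, -0.33 in HER2 D845A and -1.25 in ESR1 Y537S (adjusted p = 0.00531 in each). It changed by -0.07 in S653C (adjusted p = 0.175), -0.03 in L755S (adjusted p = 0.358), -0.04 in V777L (adjusted p = 0.440) and -0.07 in L869R (adjusted p = 0.134), and none of these passed. With neratinib the MAPK output score changed by -1.70 to -2.10 in the 4 activating mutants and by -0.89 in HER2 WT, and by -0.17 in GFP (adjusted p = 0.0252) and -0.23 in HER2 D845A (adjusted p = 0.0135). The call in GFP was lost with a pseudocount of 0.1 CPM (adjusted p = 0.0644) and with the first run set alone (adjusted p = 0.402), and that in HER2 D845A with a pseudocount of 0.1 CPM (adjusted p = 0.257). The E2F and DNA replication score changed by -1.95 to -2.76 with neratinib and by -2.85 to -3.19 with palbociclib over the 8 constructs, and the cholesterol synthesis score rose by 1.01 to 1.77 with palbociclib. Without the 2 libraries the palbociclib calls of these 2 scores were lost in GFP (adjusted p = 0.0505 in each), where 4 against 4 libraries allow fewer splits. Of the 356 camera calls over all lists and comparisons, 62.1% held with an estimated correlation, and every list call printed here without such a second p was among these.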

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

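The splits of libraries, over all libraries or within plate blocks, and the tests of depth, transcript length, BCL11B with the estrogen-induced score, the E2F and DNA replication score, GFP without 2 libraries, and estrogen-induced genes without drug were chosen after the result was seen.

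In groups of 4 to 6 libraries, a library was picked out when its gap to the nearest other library, relative to the range of the group, passed Dixon's 95% critical value. This picked out 5 libraries, in 3.91% of the groups and measures tested, and chance gives about 1 in 20 groups. ERBB2 was 25.02 CPM in replicate 1 of ESR1 Y537S DMSO, against 67.4 to 84.8 CPM in the other 5 libraries. DUSP6 was 9.33 CPM in replicate 2 of GFP DMSO, against 2.40 to 4.73 CPM. PGR was 13.8 CPM in replicate 4 of V777L DMSO, against 7.80 to 9.22 CPM. The MAPK output score was 1.83 in replicate 6 of GFP DMSO, against 2.06 to 2.16, and 1.72 in replicate 3 of L869R neratinib, against 1.85 to 1.93.

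Drug responses that differed from that in GFP by the interaction test stood out as differences between groups. For fulvestrant the test called 0.4664% of genes in HER2 WT, 0.554% in HER2 D845A, 2.74% in S653C, 2.003% in L755S, 2.25% in V777L, 0.741% in L869R and 2.45% in ESR1 Y537S. For neratinib it called 17.1% in the mean of the 4 activating mutants, 2.27% in HER2 WT and 3.54% in ESR1 Y537S. It called 7.47% for palbociclib and 9.28% for neratinib added to fulvestrant, both in the mean of the mutants.

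Chance was tested with 40 splits of the libraries of each comparison, the real one included, each fitted on the compared groups alone, where counts can differ from those of the fit on all groups. Chance could be excluded for 34 of 40 comparisons, where only the real split, 1 of 40, called as many genes. For differences in the fulvestrant response it was excluded in S653C (real 18, highest other 0), L755S (10 and 0), L869R (5 and 0) and ESR1 Y537S (73 and 0). Chance could not be excluded in V777L, where 2 of 40 splits called as many genes (real 11, highest other 42). In HER2 WT and HER2 D845A edgeR called 0 in the real split (830 and 862 at unadjusted p under 0.05, and 2 and 3 by DESeq2), so 40 of 40 splits were as large and decide nothing. For the neratinib response they were 2597 and 547 in the mean of the mutants, 22 and 0 in HER2 WT and 30 and 1 in ESR1 Y537S. In the mean of the mutants they were 620 and 1 for palbociclib and 1817 and 1 for neratinib added to fulvestrant.

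For fulvestrant within a construct, chance could not be excluded in L755S (3 of 40, real 3, highest other 1132), V777L (3 of 40, real 1, highest other 1) or L869R (2 of 40, real 13, highest other 404). The highest split in L755S had all 4 libraries of the first plate block on one side and all 4 of the third on the other, and that in L869R had the 4 of the third block on one side. Counts so far above the real ones point to a structure of the samples by plate block, so these splits measure that structure too, and with plate as block in the fit on all groups 0.0494% of genes (9) passed in L755S and 0.137% (25) in L869R. Chance is argued against by rank in S653C (real 2, highest other 0), HER2 WT (72 and 26), HER2 D845A (59 and 8) and ESR1 Y537S (2561 and 0), though S653C rests on 2 genes. The same held for the drugs in GFP, with real counts of 34 to 2116 and highest others of 0 to 2. It also held for the activating mutants against GFP, with real counts of 1368 to 3523 and highest others of 1 to 20, except 1.05% of genes for L755S. For HER2 WT (0.933% of genes in the real split) and HER2 D845A (1.05%) against GFP it held with highest others of 0, and for ESR1 Y537S with 13 (real 1755). Among the other comparisons, where it also held, the highest other was 1.48% of genes for neratinib added to fulvestrant in GFP (real 10.4%).

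The 15 fulvestrant comparisons were also split 40 ways within plate blocks, fitted on the compared groups with plate as block. For fulvestrant within a construct, chance was excluded, with only the real split, 1 of 40, calling as many genes, in GFP (real 90, highest other 1), HER2 WT (434 and 12), HER2 D845A (428 and 28), S653C (7 and 2), V777L (10 and 8), L869R (0.850% of genes, highest other 2 genes) and ESR1 Y537S (3687 and 0). It could not be excluded in L755S (2 of 40, real 35, highest other 46). For differences in the fulvestrant response it was excluded in S653C (29 and 0), V777L (20 and 0), L869R (12 and 0) and ESR1 Y537S (0.823% of genes, highest other 20 genes), but not in L755S (2 of 40, real 24, highest other 85). In HER2 WT and HER2 D845A edgeR again called 0 in the real split (1173 and 1303 at unadjusted p under 0.05, and 2 and 3 by DESeq2 without a block), so 40 of 40 splits decide nothing.

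Of the 6 GFP DMSO libraries, replicates 2 and 6 of the third plate block stood apart, with 5.88% and 6.70% mitochondrial reads against 4.55% at most elsewhere. Low depth is argued against by the 81.7% of median reads in the shallower of the 2, and loss of long transcripts by a correlation of their ratio with transcript length of -0.17, inside the -0.44 to -0.10 of the other 47 groups. Another construct, or a well of fulvestrant, is argued against by BCL11B of at least 7.27 CPM, against 0.837 CPM at most outside GFP, and by an estrogen-induced score of at least 4.65, against 4.15 at most in GFP fulvestrant. A GFP well with neratinib or palbociclib is argued against by an E2F and DNA replication score of at least 5.56, against 3.55 at most in the 4 GFP groups with either drug, and the closest group mean, which was another group for 1 of the 2, was so too for replicate 5 of GFP DMSO, which is not in doubt. What stays open is a difference in the state of those wells or in their handling, and no biological explanation was tested.

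Fulvestrant called 2177 genes in GFP but 3 to 17 in the 4 activating mutants, in the fit on all 48 groups. The size of this gap depends on the fit, since on the compared groups only 34 passed in GFP against 1 to 13 in the mutants, and more in HER2 WT (72) and HER2 D845A (59) than in GFP, while DESeq2 called 0.900% of genes in GFP against 4 to 42 genes in the mutants. With plate as block on the compared groups 90 passed in GFP, against 7, 35 and 10 in S653C, L755S and V777L but 0.850% of genes in L869R, more than in GFP. Larger spread between wells is argued against by a median SD of log2 CPM that was 0.714 times that of GFP. The 2 doubted libraries are argued against as the whole cause, since 1.94% of genes (353) passed in GFP without them in the fit on all groups, against 17 at most in a mutant, but they made up much of the GFP count. Estrogen-induced genes already lower without drug cannot be told apart from a weaker response, since the 23 that fell with fulvestrant in GFP had a median of -0.17 (quartiles -1.07 and 0.40) in the mutants against HER2 D845A, with 9 lower and 5 higher, and the 16 that fell without the 2 libraries a median of -0.60 (10 lower, 2 higher). An effect of the activating mutations on the estrogen response, which the design names, stays open as untested beyond these differences.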

How the results depend on the processing

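Settings that left out single libraries or 2 GFP DMSO libraries, list tests with plate as block, plate as block on the compared groups, and all tests of single drugs in the other constructs were chosen after the data were seen. For each of 40 comparisons the number of genes that passed was recomputed and given as a percent of 18225. This percent was called moved when it lay outside 1.5 times the reported one. With median-of-ratios (RLE) size factors, with all libraries, and with libraries of at least 30% of the median depth, the percent stayed within 1.5 times in 40 of 40 comparisons. A difference means a construct's response less that of GFP. Reported percents follow for comparisons that moved. For constructs against GFP they were 13.96% in HER2 WT, 19.1% in HER2 D845A, 35.5% in S653C, 32.1% in L755S, 35.7% in V777L, 25.1% in L869R and 25.7% in ESR1 Y537S. They were 16.8% for the mutants against HER2 WT, 3.93% for any difference among the mutants, 13.97% for neratinib added to fulvestrant in GFP, 9.28% for neratinib added to fulvestrant in the mutants less that in GFP and 16.2% for palbociclib added to fulvestrant in GFP. For drugs in GFP they were 11.9% with fulvestrant, 27.97% with neratinib, 29.4% with fulvestrant and neratinib, 22.9% with palbociclib and 29.2% with fulvestrant and palbociclib. For fulvestrant response differences they were 0.4664% in HER2 WT, 0.554% in HER2 D845A, 2.74% in S653C, 2.003% in L755S, 2.25% in V777L, 0.741% in L869R and 2.45% in ESR1 Y537S. For neratinib response differences they were 17.1% in the mutants, 2.27% in HER2 WT and 3.54% in ESR1 Y537S. For palbociclib response differences they were 7.47% in the mutants. For fulvestrant in the other constructs they were 0.263% in HER2 WT, 0.296% in HER2 D845A, 0.0165% in S653C, 0.0165% in L755S, 0.0165% in V777L, 0.0933% in L869R and 14.03% in ESR1 Y537S.

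DESeq2 on the compared groups moved 26 of 40, 20 lower and 6 higher, and the cause was not tested. DESeq2 gave for constructs against GFP 2.88% in HER2 WT, 4.203% in HER2 D845A, 19.4% in L755S, 22.8% in V777L, 11.4% in L869R and 13.5% in ESR1 Y537S. DESeq2 gave for drugs in GFP 0.8999% with fulvestrant, 14.6% with neratinib, 14.1% with fulvestrant and neratinib, 8.63% with palbociclib and 16.2% with fulvestrant and palbociclib. DESeq2 gave for fulvestrant response differences 0.01097% in HER2 WT, 0.0165% in HER2 D845A, 0.302% in S653C, 0.187% in L755S, 0.214% in V777L, 0.115% in L869R and 1.11% in ESR1 Y537S. DESeq2 gave for fulvestrant in the other constructs 0.636% in HER2 WT, 0.691% in HER2 D845A, 0.0274% in S653C, 0.0384% in L755S and 0.2304% in L869R. DESeq2 gave 6.67% for any difference among the mutants, and for neratinib response differences 0.351% in HER2 WT and 0.609% in ESR1 Y537S.

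With edgeR fitted on the compared groups only, 23 of 40 moved and all 23 were lower. Of these 22 use the GFP DMSO libraries, and the median SD of log2 CPM was 0.383 in GFP against 0.274 in the mutants, in DMSO and fulvestrant. The smaller fit gave for constructs against GFP 0.933% in HER2 WT, 1.05% in HER2 D845A, 19.3% in S653C, 14.3% in L755S, 18.4% in V777L, 7.51% in L869R and 9.63% in ESR1 Y537S. The smaller fit gave for drugs in GFP 0.187% with fulvestrant, 10.04% with neratinib, 10.2% with fulvestrant and neratinib, 5.22% with palbociclib and 11.6% with fulvestrant and palbociclib. The smaller fit gave for fulvestrant response differences 0% in HER2 WT, 0% in HER2 D845A, 0.0988% in S653C, 0.0549% in L755S, 0.0604% in V777L, 0.0274% in L869R and 0.401% in ESR1 Y537S. The smaller fit gave for neratinib response differences 0.121% in HER2 WT and 0.165% in ESR1 Y537S, and for palbociclib response differences 3.402% in the mutants, and for fulvestrant in the other constructs 0.00549% in V777L. At unadjusted p under 0.05, 830 and 862 genes passed in the smaller edgeR fit where 0 passed after adjustment, and DESeq2 called 2 and 3 there.

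With the first run set alone, which holds fewer reads by construction, 26 of 40 moved and all 26 were lower, so depth limited these counts. This depth gave for constructs against GFP 7.68% in HER2 WT, 10.8% in HER2 D845A, 15.6% in L869R and 17.1% in ESR1 Y537S. This depth gave 10.1% for the mutants against HER2 WT, 2.39% for any difference among the mutants, 7.86% for neratinib added to fulvestrant in GFP, 4.72% for neratinib added to fulvestrant in the mutants less that in GFP and 10.2% for palbociclib added to fulvestrant in GFP. This depth gave for drugs in GFP 6.35% with fulvestrant, 19.4% with fulvestrant and neratinib and 15.2% with palbociclib. This depth gave for fulvestrant response differences 0.165% in HER2 WT, 0.148% in HER2 D845A, 1.19% in S653C, 0.477% in L755S, 0.818% in V777L, 0.296% in L869R and 0.971% in ESR1 Y537S. This depth gave for neratinib response differences 10.1% in the mutants, 1.06% in HER2 WT and 1.44% in ESR1 Y537S. This depth gave for fulvestrant in the other constructs 0.143% in HER2 WT, 0.132% in HER2 D845A and 8.14% in ESR1 Y537S. This depth gave for palbociclib response differences 3.96% in the mutants.

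Without a low-count filter, which raises the genes tested to 49198, 11 of 40 moved and all 11 were lower. No filter gave for fulvestrant response differences 0.0933% in HER2 WT, 0.121% in HER2 D845A, 1.22% in S653C, 0.642% in L755S, 0.894% in V777L, 0.258% in L869R and 1.39% in ESR1 Y537S. No filter gave for drugs in GFP 7.26% with fulvestrant, and for neratinib response differences 1.16% in HER2 WT and 1.65% in ESR1 Y537S, and for palbociclib response differences 4.46% in the mutants.

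Plate as replicate block moved 17 of 40, and all 17 were higher, though the labels do not say that a number marks a shared plate. Libraries of different groups had a median residual correlation of 0.15 within a plate block and -0.11 between blocks, which is a hint from the data. The block gave 7.24% for any difference among the mutants and 14.01% for neratinib added to fulvestrant in the mutants less that in GFP. The block gave for fulvestrant response differences 3.204% in HER2 WT, 3.599% in HER2 D845A, 7.13% in S653C, 6.003% in L755S, 6.07% in V777L, 3.59% in L869R and 5.701% in ESR1 Y537S. The block gave for fulvestrant in the other constructs 0.872% in HER2 WT, 0.571% in HER2 D845A, 0.0329% in S653C and 0.0494% in L755S. The block gave for drugs in GFP 18.2% with fulvestrant, and for neratinib response differences 5.48% in HER2 WT and 8.56% in ESR1 Y537S, and for palbociclib response differences 15.1% in the mutants. Among list calls it ended that of fibroblast, blood and vessel genes with palbociclib in GFP (adjusted p = 0.0710) and changed no other list result printed in the report.

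Plate as block on the compared groups only was run for 15 fulvestrant comparisons. This fit gave for fulvestrant response differences 0% in HER2 WT, 0% in HER2 D845A, 0.159% in S653C, 0.132% in L755S, 0.1097% in V777L, 0.0658% in L869R and 0.823% in ESR1 Y537S. This fit gave for fulvestrant in the other constructs 2.38% in HER2 WT, 2.35% in HER2 D845A, 0.0384% in S653C, 0.192% in L755S, 0.0549% in V777L and 0.8505% in L869R. This fit gave for drugs in GFP 0.494% with fulvestrant. At unadjusted p under 0.05 edgeR called 1173 and 1303 genes there where 0 passed after adjustment, and DESeq2 without a block called 2 and 3.

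Without the 2 GFP DMSO libraries of the third plate block (replicates 2 and 6), 16 of the 23 comparisons that use GFP DMSO moved and all 16 were lower. Leaving out 1 of the other 4 GFP DMSO libraries raised percents where it moved them, so fewer libraries are not the whole cause. The other libraries gave for drugs in GFP 1.94% with fulvestrant, 17.4% with neratinib and 18.2% with fulvestrant and palbociclib. The other libraries gave for fulvestrant response differences 0% in HER2 WT, 0% in HER2 D845A, 0.263% in S653C, 0.214% in L755S, 0.236% in V777L, 0.143% in L869R and 0.955% in ESR1 Y537S. The other libraries gave for neratinib response differences 8.49% in the mutants, 0.472% in HER2 WT and 0.598% in ESR1 Y537S. The other libraries gave for constructs against GFP 5.23% in HER2 WT and 5.51% in HER2 D845A, and for palbociclib response differences 2.08% in the mutants. At unadjusted p under 0.05 edgeR called 700 and 851 genes where 0 passed after adjustment, and DESeq2 with all kept libraries called 2 and 3.

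Each library of GFP DMSO and of the groups with 4 or 5 libraries was also left out in turn, with the dispersion trend held. The lowest and highest percents are given for 15 comparisons in which at least 1 library moved the count. The range was, for constructs against GFP, 6.16% to 18.6% in HER2 WT and 9.76% to 23.6% in HER2 D845A. The range was, for drugs in GFP, 3.199% to 16.9% with fulvestrant. The range was, for fulvestrant response differences, 0.00549% to 3.76% in HER2 WT, 0% to 3.78% in HER2 D845A, 0.444% to 6.46% in S653C, 0.2798% to 5.51% in L755S, 0.346% to 5.53% in V777L, 0.159% to 3.28% in L869R and 1.07% to 4.499% in ESR1 Y537S. The range was, for neratinib response differences, 10.3% to 20.3% in the mutants, 0.499% to 5.11% in HER2 WT and 0.905% to 6.23% in ESR1 Y537S. The range was, for palbociclib response differences, 2.31% to 11.4% in the mutants. The range was, for fulvestrant in the other constructs, 0.00549% to 0.01097% in V777L.

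Without GFP DMSO replicate 6 it was for constructs against GFP 6.16% in HER2 WT and 9.76% in HER2 D845A, and for drugs in GFP 3.199% with fulvestrant. Without GFP DMSO replicate 6 it was for fulvestrant response differences 0.00549% in HER2 WT, 0% in HER2 D845A, 0.444% in S653C, 0.2798% in L755S, 0.346% in V777L, 0.159% in L869R and 1.07% in ESR1 Y537S, and for neratinib response differences 10.3% in the mutants, 0.499% in HER2 WT and 0.905% in ESR1 Y537S. Without GFP DMSO replicate 6 it was for palbociclib response differences 2.31% in the mutants. There edgeR called 0 genes in HER2 D845A (910 at unadjusted p under 0.05), and DESeq2 with all kept libraries called 3. Leaving out replicate 2 it was for constructs against GFP 9.15% in HER2 WT, and for drugs in GFP 6.95% with fulvestrant. Leaving out replicate 2 it was for fulvestrant response differences 0.115% in HER2 WT, 0.137% in HER2 D845A, 1.32% in S653C, 0.818% in L755S, 0.927% in V777L and 0.313% in L869R, and for neratinib response differences 1.23% in HER2 WT and 1.79% in ESR1 Y537S. Leaving out replicate 2 it was for palbociclib response differences 4.78% in the mutants. Without GFP palbociclib replicate 2 it was for palbociclib response differences 4.66% in the mutants. Without V777L fulvestrant replicate 1 it was for fulvestrant response differences 1.32% in V777L, and for fulvestrant in the other constructs 0.00549% in V777L. Without V777L fulvestrant replicate 4 it was for fulvestrant response differences 1.202% in V777L.

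The other 4 GFP DMSO libraries raised percents when left out, where they moved them. Without GFP DMSO replicate 5 it was for fulvestrant response differences 3.76% in HER2 WT, 3.78% in HER2 D845A, 6.46% in S653C, 5.51% in L755S, 5.53% in V777L, 3.28% in L869R and 4.499% in ESR1 Y537S, and for neratinib response differences 5.11% in HER2 WT and 6.23% in ESR1 Y537S. Without GFP DMSO replicate 5 it was for palbociclib response differences 11.4% in the mutants. Leaving out replicate 4 it was for fulvestrant response differences 2.56% in HER2 WT, 2.11% in HER2 D845A, 5.35% in S653C, 4.12% in L755S, 4.02% in V777L, 2.29% in L869R and 4.26% in ESR1 Y537S, and for neratinib response differences 3.91% in HER2 WT and 5.49% in ESR1 Y537S. For replicate 3 it was for fulvestrant response differences 1.86% in HER2 WT, 1.54% in HER2 D845A, 4.16% in S653C, 3.07% in L755S, 1.696% in L869R and 4.18% in ESR1 Y537S, and for neratinib response differences 5.38% in ESR1 Y537S. For replicate 1 it was for fulvestrant response differences 1.14% in HER2 WT, 1.01% in HER2 D845A and 1.23% in L869R.

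Named genes kept their direction and side of the threshold in 98.9% of 1640 recomputed values, with 0 reversed and 18 weaker. Of the 18, 7 were IGFBP5 with fulvestrant in V777L, 6 IGFBP5 in S653C, 3 GREB1 in ESR1 Y537S, 1 CISH in L755S and 1 S100A7A in V777L. Of the list results in the report, 11 calls were lost with an estimated correlation, 3 lists passed with fry only, 4 calls were lost without the 2 GFP DMSO libraries, and 0 reversed.

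For 40 list scores with up to 5 alternatives each, 5 calls were lost by exact permutation and 0 reversed. The MAPK output score with neratinib in GFP changed by -0.25 with a pseudocount of 0.1 CPM (adjusted p = 0.0644) and by -0.091 with the first run set alone (adjusted p = 0.402), in a range of 0.0106 to 0.402. In HER2 D845A it changed by -0.24 with a pseudocount of 0.1 CPM (adjusted p = 0.257, range 0.00496 to 0.257). Without the 2 GFP DMSO libraries, palbociclib in GFP changed the E2F and DNA replication score by -2.84 and the cholesterol synthesis score by 1.31 (adjusted p = 0.0505 in each, range 0.00992 to 0.0505), where 4 against 4 libraries allow fewer splits by construction. The cause of the other 3 was not tested.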

Other observations

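The test of single genes near BCL11B was chosen after the result was seen. BCL11B, a transcription factor gene, was higher in each of the 34 GFP libraries than in any kept library of the other 7 constructs. It averaged 18.7 CPM in GFP and 0.105 CPM in the other constructs over all drugs, a difference of 7.49 ± 0.13, with 7.27 CPM in the lowest GFP library and 0.837 CPM in the highest other one. Among genes with a mean of at least 10 CPM, 1 locus without a gene name was the only other one set apart in this way (36.3 against 0.217 CPM), and 0 genes were lower in GFP in this way. Every comparison with GFP therefore carries these 2 genes whatever the construct. Extra copies of the region are argued against, since the 10 tested genes nearest to BCL11B had a median log2 fold change of 0.052. A change at one place of the genome, such as an insertion, may explain part of it and cannot be told apart from a different history of the GFP cells, since 1 of the 10 nearest genes was over 2-fold higher, CCDC85C at 4.06 ± 0.08 (27.2 against 1.64 CPM). No biological explanation was tested.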
